A study of Mus musculus with 4 samples.

How the data were processed

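Single-cell RNA libraries made on the 10x Genomics platform from FACS-sorted CD45+ cells of mice at day 7 of infection were analysed, 1 library each from brain, galea, bone flap and blood. Whether animals were pooled is not stated, and no uninfected samples were among those given. The authors processed the reads with Cell Ranger 3.0.0 against build mm10, and the deposited matrices hold raw UMI counts per gene and barcode for 31053 genes, with no normalization; the smallest barcode in each file has 500 UMIs. The 36 repeated gene symbols were kept apart by their identifier. Gene positions were taken from GENCODE vM21 on the same build.

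Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 956 barcodes in brain, 55 in galea, 22 in bone flap and 2891 in blood. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 6%), which removed 323, 1, 2 and 426 cells; with calls of 1 and 2 cells in galea and bone flap the caller is taken as not having worked there, and doublets in these libraries are not excluded. The 37106 remaining cells were scaled, log-transformed and clustered together on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2), giving 33 clusters. Clusters were named by the scores of fixed marker sets of cell types, and 4 clusters stayed unnamed. Of the 21 sets, the proliferation set is not a cell type and was not scored. A cluster stayed unnamed when most markers of another type were also raised in it, or when its 10 leading genes held more markers of another type than of its own, the latter except between microglia and macrophages, which share markers. Shares have exact Clopper-Pearson 95% intervals. Because each site has 1 library, no test between sites was made. Intervals and floors cover counting error only, not differences between animals or preparations.

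For each class with at least 50 cells in both libraries of a pair, 19 pairs in all, UMIs were summed and expressed as CPM, and the log2 ratio of CPM + 5 was computed. A gene was counted when it was at least 4-fold apart with at least 50 CPM and 30 UMIs in the higher library. These counts had no limit against free RNA, that is RNA from another class, and may include such genes. Folds are ratios of CPM with exact 95% intervals, and a fold against 0 UMIs is a lower bound against 3 counts. Genes named are the 10 with the highest and the 10 with the lowest log2 ratio of each pair, if 2-fold apart, above the same floors, and at or above 1/5 of their highest CPM in any class of the same library, so that free RNA from another class was not named; mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor segment, sex-linked marker and predicted genes were left out. From each described list up to 4 members with the largest ratios were added. There were 31 gene lists; members with at least 20 CPM in the higher library counted as measured, lists with at least 4 such members were described, members at least 2-fold apart were counted, and the median was placed among those of 10000 random lists matched in 20 bins of expression. These rules and lists were written before the data were examined; which lists to describe for each pair was chosen afterwards. The lectin gene Clec7a is not among the deposited genes and was not used.

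In a test on simulated data, 100 genes were given an 8-fold difference. Of these, 97 to 99 were called at 4-fold in the right direction in each of 4 comparisons. Of 100 genes given a 2-fold difference 0 were called, and no unaltered gene was called. Such genes lie below the 4-fold limit, so these results do not show how often calls in the real data are wrong. The test gives no measure of the effects of scaling, free RNA, doublets or mixed classes.

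Alternatives were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0, R 4.3.3), the mean of each cell's CPM, cells thinned to 1000 UMIs, a pseudocount of 1, no floor beyond 3 UMIs, a stricter cell filter (500 genes, 5% mitochondrial), no cell filter, doublets kept, Leiden resolutions of 0.5 and 2, and each library clustered on its own. After the data were seen, 2 alternatives were added: leaving out barcodes found in more than 1 library, and also removing the highest doublet scores in galea and bone flap. A barcode was called a copy when another library held it with at least 10 times its UMIs. The pseudocount and scaling were varied on fixed classes. Thinning equalized the UMIs per cell, not the sums of the classes, in which the minimum of 30 UMIs then stands for different CPM. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.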

Results

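CD45+ cells, that is cells bearing the pan-leukocyte surface protein, were sorted from mice 7 days after infection of a craniotomy with the bacterium Staphylococcus aureus and sequenced as single cells from 4 sites: the brain, the galea (the tissue layer under the scalp), the bone flap (the piece of skull removed and put back) and the blood. Each site had 1 library, so there were no replicates, and differences between sites are given as sizes with intervals that cover counting error only. The files held 11122 cell barcodes from brain, 11932 from galea, 6785 from bone flap and 11943 from blood, each with at least 500 UMIs (unique molecular identifiers, counts of single RNA molecules). The total was 91410136 UMIs in brain, 30402934 in galea, 30065338 in bone flap and 63445333 in blood, and the median barcode had 6572, 2124, 4398 and 4580 UMIs. After removal of damaged cells and called doublets 9843, 11876, 6761 and 8626 cells were compared. Levels are given as CPM, the UMIs of a gene summed over the cells of a class and scaled to the same total in every class.

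The first question was which leukocytes were found at each site. Clusters were named only by markers fixed beforehand, so that a neutrophil here is a neutrophil-like cell with genes such as S100a8, S100a9 and Csf3r, and likewise for the other classes. Neutrophils made up 88.2% of the galea cells (10470 cells, exact Clopper-Pearson 95% interval 87.6 to 88.7%) and 97.4% of the bone flap cells (6585 cells, 97.0 to 97.8%), against 8.14% in brain (801 cells, 7.60 to 8.70%) and 13.3% in blood (1149 cells, 12.6 to 14.1%). Brain held 2893 cells in the class named microglia, the resident macrophages of the brain, a share of 29.4% (28.5 to 30.3%), 2097 T cells (21.3%, 20.5 to 22.1%) and 1337 other macrophages (13.6%, 12.9 to 14.3%). Of the microglia class 1456 cells lay in a cluster led by P2ry12 and Tmem119, but 1149 and 288 lay in 2 clusters led by Ccl12, whose 10 leading genes held more macrophage markers, such as C1qa and C1qb, than microglia markers, so the name is uncertain for these. A further 909 brain cells (9.23%) were left unnamed, among them a cluster of 388 led by Apoc1, Apoe and C1qa that entered neither the microglia nor the macrophage class. Blood held 3701 B cells (42.9%, 41.9 to 44.0%), 1935 T cells (22.4%, 21.6 to 23.3%) and 1124 natural killer (NK) cells (13%, 12.3 to 13.8%). No cell of the microglia class was called among the 8626 blood cells, which allows at 3 cells of the total a share of up to 0.0348%. Macrophages were 4.99% of galea cells and 0.991% of bone flap cells. Of the 35 blood barcodes in the macrophage class, 32 were low-UMI copies of a barcode of another library. Immature granulocytes, which carry Camp and Ltf, numbered 291 in brain (2.96%, 2.63 to 3.31%), 141 in galea, 10 in blood and 0 in bone flap. Their number in brain was 237 at Leiden resolutions of 0.5 and 2, 230 with the stricter filter and 234 without shared barcodes. It was 33 with called doublets kept, without a cell filter or with the highest doublet scores removed, and 36 with each library clustered on its own. The size of this class thus differed between settings. In the main clustering 258 of the 291 brain cells lay in a cluster led by Mmp8 and Ltf. Its 10 leading genes held 3 markers of the class and up to 2 of another type. The other 33 lay in a cluster with 7 markers of the class and 0 of another type. With doublets kept 211 galea cells were unnamed, against 52 in the main clustering. Why the larger group was not always named was not tested. The shares describe sorted CD45+ cells above the minimum of 500 UMIs and may depend on the median depth, which differed between libraries. Shares at equal depth were not computed. With each library clustered on its own the brain macrophage share was 6.64%, and with at least 500 genes and at most 5% mitochondrial UMIs per cell the blood shares were 24.8% neutrophils and 22.6% B cells.

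**Figure D1:**
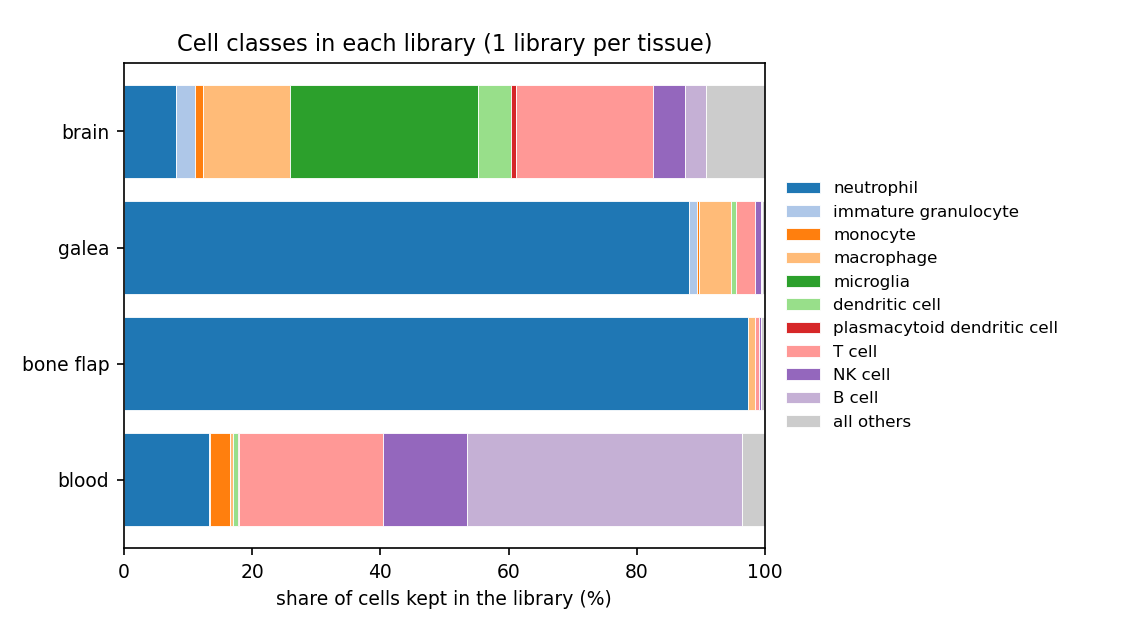
Share of the kept cells (x axis, %) in each cell class (colours) for the 4 libraries (1 bar per library). Neutrophils fill 88.2% of the galea bar and 97.4% of the bone flap bar, against 8.14% in brain and 13.3% in blood.

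The neutrophils of each tissue were compared with those of blood. Cxcl2 and Cxcl3, which encode chemokines that attract neutrophils, were far higher in tissue. Cxcl2 (ENSMUSG00000058427, a protein-coding gene on chromosome 5 from 90903871 to 90905938, mm10) was at 11861 CPM in brain, 49963 in galea and 51855 in bone flap against 167 in blood, or 71.1-fold (65.7 to 77.0), 299.6-fold (277 to 324) and 311-fold (288 to 337) higher. Cxcl3 (ENSMUSG00000029379, chromosome 5 from 90786103 to 90789600) was 68.3-fold (47.0 to 103), 517-fold (357 to 778) and 554-fold (383 to 833) higher. Ccl3 and Ccl4, which encode chemokines for monocytes and T cells and lie next to each other on chromosome 11, were 81.9-fold and 49.8-fold higher in brain, 132-fold and 216-fold in galea, and 372-fold and 239-fold in bone flap. The interleukin-1 alpha gene Il1a was at 81.2, 818 and 1324 CPM against 2.37 in blood, and Tnf, the gene of tumour necrosis factor, at 134, 774 and 689 against 6.05. Spp1 (osteopontin) was 43.0-fold, 353-fold and 334-fold higher, with 53.3% of its brain UMIs in 5 of 801 cells. F3, the gene of tissue factor, had 10975 UMIs in bone flap neutrophils and 0 in blood, at least 492-fold higher against a floor of 3 counts in the class.

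Genes lower in tissue neutrophils than in blood included Itga4, an integrin subunit used in leaving the blood, which was 4.71-fold (4.09 to 5.45) lower in brain, 27.0-fold (23.8 to 30.6) in galea and 51.8-fold (44.8 to 60.1) in bone flap. The kinase gene Mapk14 was 29.0-fold lower in galea and 44.9-fold in bone flap, and the DNA repair gene Xpc was 5.78-fold lower in brain and 23.9-fold in galea. In all, 100 genes were at least 4-fold higher and 17 at least 4-fold lower in brain, 200 and 484 in galea, and 223 and 543 in bone flap. TMM scaling, which sets the typical gene to no difference, moved log2 ratios by 1.08 in galea and 1.28 in bone flap, and by -0.02 in brain. It gave 487 genes higher and 107 lower in galea, and 619 higher and 126 lower in bone flap. Median-of-ratios scaling gave 459 and 124, and 598 and 137. Of the galea genes called on CPM 307 were also called after TMM scaling, and of the bone flap genes 349. Blood neutrophils lay almost entirely in 1 cluster that also held 256 of the 801 brain neutrophils, 113 galea and 4 bone flap cells. With every cell weighted equally 3 of 56 named genes in brain, 5 of 58 in galea and 6 of 58 in bone flap moved by over 1.5 times, among them Cxcl2 and Cxcl3. The log2 ratio of Cxcl2 was then 5.14 in brain, 7.00 in galea and 7.02 in bone flap, against 6.11, 8.18 and 8.24 from summed UMIs, and that of Cxcl3 3.65 in brain, 6.22 in galea and 6.32 in bone flap, against 5.36, 8.27 and 8.37 from summed UMIs.

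**Figure D2:**
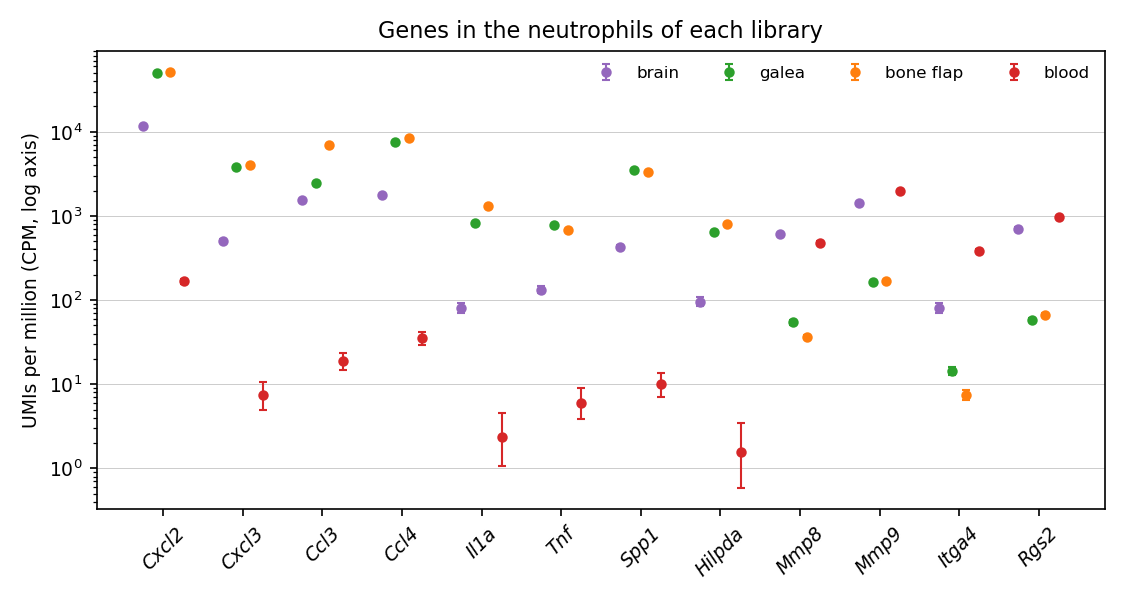
CPM (y axis, log scale) of 12 genes in the neutrophils of the 4 libraries (colours); bars are exact 95% Poisson intervals of the counts. Cxcl2 lies at 167 CPM in blood and between 11861 and 51855 in the tissues, and Itga4 at 384 in blood and between 7.42 and 81.5 in the tissues.

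Gene lists fixed in advance were compared by the median log2 ratio of their members to blood. Of 15 measured genes of the hypoxia response, 12 were at least 2-fold higher in neutrophils of each tissue and 2 lower in galea and in bone flap, with medians of 1.36 in brain, 2.84 in galea and 2.37 in bone flap (1.32, 3.79 and 3.49 after TMM scaling). Hilpda, a lipid droplet gene induced at low oxygen, was at 95.5, 650.1 and 799 CPM against 1.58 in blood, and Ero1l at 167, 1151 and 1095 against 17.6. Of 15 glycolysis genes 8 were higher in brain and 12 in galea and in bone flap (medians 1.04, 2.22 and 2.08), with the enzyme gene Tpi1 at 317, 1101 and 1222 CPM against 52.1. Chemokines for mononuclear cells had medians of 2.53, 3.09 and 4.37, with 5 of 8, 6 of 8 and 5 of 7 members higher and 1, 2 and 2 lower. Proinflammatory cytokines had medians of 1.40, 2.14 and 2.03 (1 member lower in galea and 1 in bone flap), and inflammasome and interleukin-1 genes of 0.32, 1.38 and 1.42. In the cell death and stress list, with Ddit4 and Gadd45b among the largest ratios, the medians were 1.12, 2.05 and 1.96, with 1 member lower in galea and 1 in bone flap. The Toll-like receptor list had medians of 0.44, 0.36 and 0.73 (1.39 in galea and 1.98 in bone flap after TMM scaling). Its members went both ways: 5 of 14 higher in brain, 5 higher and 4 lower of 14 in galea, and 7 higher and 4 lower of 15 in bone flap. In this list the co-receptor gene Cd14 was at 1095, 5221 and 6464 CPM against 178. Interferon-stimulated genes had medians of 0.58, 0.34 and 0.63, with 7 of 20, 6 of 19 and 7 of 20 higher and 0, 2 and 1 lower (medians of 1.41 in galea and 1.71 in bone flap after TMM scaling), with Gbp5 at 128, 443 and 607 CPM against 13.9. The galea median of that list was 0.05 without 1 member that was more than 5 times higher in another class. Tissue remodelling genes had medians of 2.37 in galea and 2.54 in bone flap, with 5 of 8 higher and 1 lower in each. For these 9 lists the median lay at or above the 97.9th percentile of 10000 random lists of matched level at each site where it is given. Which of the 31 lists to describe here was chosen after the results were seen, so these percentiles are descriptive.

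For other lists the direction differed between sites or scalings. The gelatinase granule list, which includes the metalloproteinase genes Mmp8 and Mmp9, had a median of 0.05 in brain, -0.90 in galea and -0.58 in bone flap, and of 0.17 in galea and 0.68 in bone flap after TMM scaling. Mmp9 was at 1435 CPM in brain, 165 in galea and 170.5 in bone flap against 1999 in blood, and Mmp8 at 605, 54.3 and 36.2 against 483. Oxidative phosphorylation genes had medians of 0.17 in brain, -0.84 in galea and -1.15 in bone flap, with 9 of 22 members at least 2-fold lower in galea and 14 of 22 in bone flap. After TMM scaling those medians were 0.18 in galea and 0.08 in bone flap, so their direction was set by the scaling. Free RNA was seen in brain: C1qa, a microglia and macrophage gene, had a UMI in 42.7% of brain neutrophils (304 CPM, median depth 3234 UMIs) and in 0.478% of galea neutrophils (2.36 CPM, median depth 2034 UMIs). It was also seen in blood: Cd79a, a B cell gene, had a UMI in 12.7% of blood neutrophils (51.3 CPM) and in 0.105% of galea neutrophils (0.726 CPM). The counts of 4-fold genes against blood were not filtered for free RNA. They thus include C1qa as higher in brain and Cd79a as lower in galea and bone flap.

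**Figure D3:**
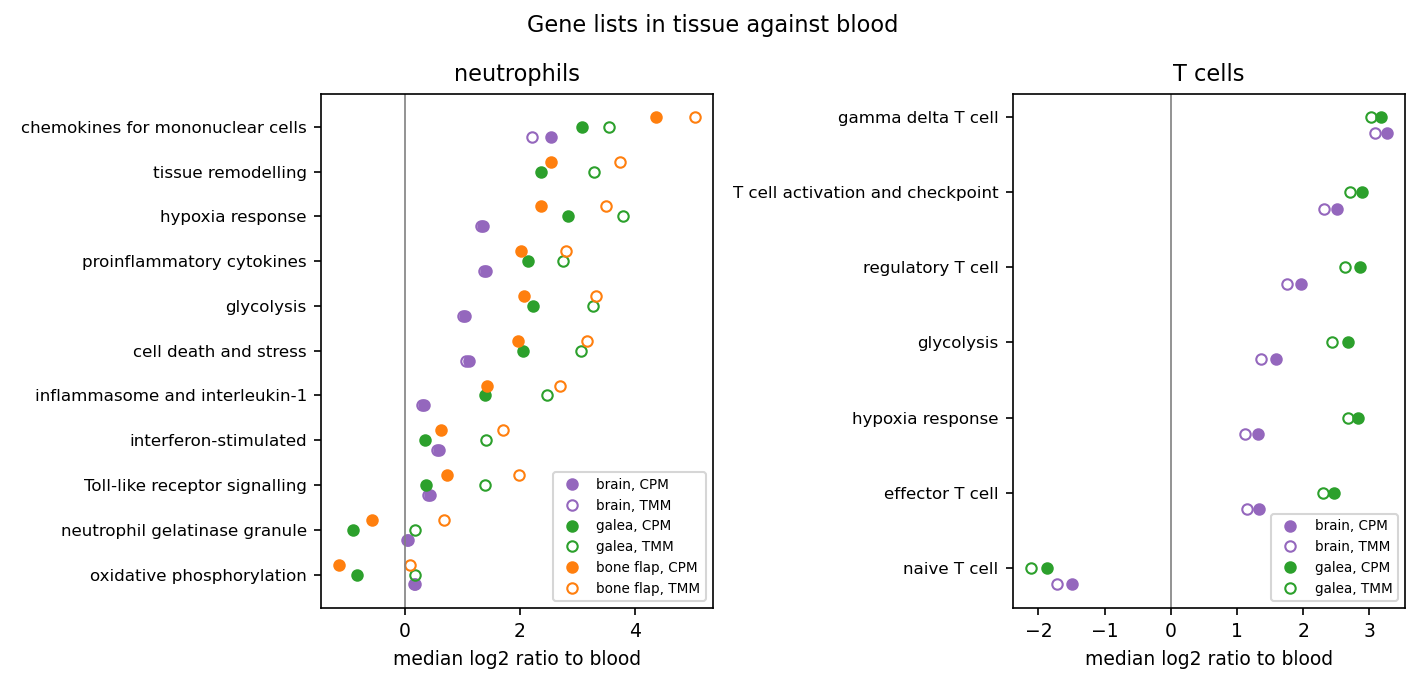
Median log2 ratio to blood (x axis) of the members of each fixed gene list (y axis) in neutrophils (left) and T cells (right); colours are tissues, filled points are CPM and open points TMM scaling. In neutrophils the hypoxia response list lies at 1.36, 2.84 and 2.37 on CPM, while the oxidative phosphorylation list crosses 0 with the scaling in galea and bone flap.

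Neutrophils of the galea and the bone flap were close to each other. Only 2 genes were at least 4-fold higher and 1 at least 4-fold lower in galea (2 and 2 after TMM scaling, which moved ratios by -0.20; 1 and 2 after median-of-ratios scaling). Lars2, the mitochondrial leucyl-tRNA synthetase gene, was 4.63-fold (4.50 to 4.76) higher in galea and Fosb, an immediate early gene, 3.46-fold (3.12 to 3.84). Lower in galea were the stress-induced gene Gadd45b (1557 against 5330 CPM, 3.42-fold), Ccl3 (2.81-fold), the lectin receptor gene Clec4d (2.61-fold) and the chemokine receptor gene Cxcr4 (2.41-fold). The hypoxia response list had a median of 0.01, with none of 15 members 2-fold apart, glycolysis -0.05, with none of 15, and proinflammatory cytokines -0.22, with none of 8. Of 17 immediate early and dissociation genes 1 was at least 2-fold higher (Fosb) and 2 lower (Hsp90aa1 and Hspa1b), with a median of 0.23. The median galea neutrophil had 2034 UMIs and the median bone flap neutrophil 4390.

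Brain neutrophils were next compared with those of galea. Against galea, 193 genes were at least 4-fold higher and 41 lower. Genes of other classes were not removed from these counts: C1qa, at 304 CPM in brain and 2.36 in galea neutrophils, is among those higher in brain. TMM scaling moved ratios by -1.10 and gave 17 higher and 256 lower, and median-of-ratios scaling 21 and 235, with 58 and 62 of the genes called on CPM among them. Mmp8 was 11.1-fold (10.3 to 12) higher in brain, Mmp9, also a marker used to name the class, 8.71-fold (8.32 to 9.12) and the signalling regulator gene Rgs2 12.2-fold (11.3 to 13.1). With called doublets kept the log2 ratio of Mmp8 was 2.11 instead of 3.36. Lower in brain were Il1a (10.1-fold, 8.82 to 11.6), Spp1 (8.21-fold), F3 (9.07-fold), Cxcl3 (7.56-fold) and the superoxide dismutase gene Sod2 (6.26-fold). The hypoxia response list had a median of -1.01 with 8 of 15 members lower and 2 higher, glycolysis -1.02 with 8 of 15, tissue remodelling -1.06 with 4 of 8 lower and 1 higher, cell death and stress -0.86 with 5 of 12, and chemokines for mononuclear cells -0.69 with 4 of 9 lower and 1 higher (0.20 when every member with at least 3 UMIs is used). Interferon-stimulated genes had a median of 0.20 with 7 of 20 higher and 5 lower (-0.88 after TMM scaling), the gelatinase granule list 0.96 (0.16, or -0.19 when its measured members are chosen anew after the scaling) and oxidative phosphorylation 0.95 (-0.12). The 2 groups lay mostly in different clusters: of 801 brain neutrophils 373 fell in a cluster led by the interferon-stimulated genes Rsad2 and Ifit1, with 640 of the 10470 galea cells, and 256 in the main blood cluster. Clusters of 3712, 2793, 2202 and 1009 galea cells held 80, 35, 26 and 31 brain cells.

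Brain macrophages, microglia excluded, differed widely from galea macrophages. Gpnmb, the gene of a transmembrane glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6 from 49036546 to 49070929), was at 501 CPM in brain against 12 in galea, 41.8-fold (31.7 to 56.3) higher. The apolipoprotein gene Apoe (ENSMUSG00000002985, chromosome 7 from 19696109 to 19699188) was at 24658 against 1480 CPM, 16.7-fold (16.2 to 17.1) higher, the fatty acid binding protein gene Fabp5 7.26-fold and Axl, a receptor for dying cells, 7.28-fold. Lower in brain were Cxcl3 (10.6 against 1948 CPM, 184-fold), the metalloproteinase gene Mmp12 (63.7-fold, 54.5 to 74.9), the protease inhibitor gene Slpi (43.8-fold), Pdpn (56.5-fold), the prostaglandin E synthase gene Ptges (61.1-fold), Inhba (39.0-fold), Il1a (28.7-fold), Nos2, which encodes inducible nitric oxide synthase (20.7-fold, 18.5 to 23.2), Spp1 (17.2-fold) and Clec4n (16.8-fold). Of 8 genes of MHC class II antigen presentation 6 were at least 2-fold higher in brain, among them Ciita (158 against 34.1 CPM) and H2-Ab1 (6490 against 1714 CPM), with a median of 1.40. Proinflammatory cytokines had a median of -2.38, with 5 of 6 lower, among them Tnf (22.8 against 192 CPM) and Csf3. Chemokines for mononuclear cells had a median of -0.99 (6 of 13 lower, 1 higher), the hypoxia response -0.78 (7 of 15), glycolysis -0.78 (6 of 15), myeloid suppressor genes -0.67 (8 of 18, 2 higher) and tissue remodelling -0.62 (6 of 14, 1 higher). The disease-associated microglia list had a median of 0.77 (7 of 15 higher, 5 lower), with Gpnmb, Apoe and Fabp5 higher and Spp1 lower, the lipid handling list 0.61 (3 of 12 higher, 2 lower), with Lpl 9.28-fold lower, and phagocytic and complement receptors -0.06 (-0.41 after TMM scaling).

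In total 42 genes were at least 4-fold higher and 74 lower in brain than in galea macrophages. TMM scaling moved ratios by -0.35 and gave 18 and 100, and median-of-ratios scaling 18 and 102. Of the brain cells 1288 lay in 1 cluster with 194 galea cells, and 399 galea cells lay in another with 63 of the 67 bone flap macrophages. At a finer clustering (resolution 2) 179 genes were 4-fold apart, and with every cell weighted equally 9 of 47 named genes moved by over 1.5 times, with the log2 ratio of Cxcl3 at -4.86 instead of -6.97. Apoe, Gpnmb and Spp1 are also among the markers used to name the class. Among the genes lower in brain, Cxcl3, Il1a and Tnf are also genes of galea neutrophils (3805, 818 and 774 CPM there). Doublets in galea are not excluded, so neutrophil RNA was not separated from the differences between brain and galea macrophages.

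Galea and bone flap macrophages were compared on 593 and 67 cells. The monocyte chemokine genes Ccl2 (13.9-fold, 8.52 to 24.4) and Ccl7 (17.3-fold, 7.90 to 47.5) were higher in galea, and Ccl8 had 383 UMIs in galea and 0 in bone flap, at least 27.8-fold higher, with 89.0% of the UMIs in 5 of 593 cells. The complement gene C1qb, also a marker used to name the class, was 6.09-fold (5.08 to 7.35) higher. In bone flap the heat shock genes Hspa1a (16.2-fold) and Hspa1b (10.9-fold), Gpnmb (14.2-fold), Ccl3 (5.24-fold) and Cxcl1 (4.55-fold) were higher, but the 5 richest cells held 88.9%, 86.9%, 69.7%, 63.9% and 96.1% of the UMIs of these genes. Of 13 chemokines for mononuclear cells 6 were higher and 3 lower in galea (median 0.81). Interferon-stimulated genes had a median of 0.69 (6 of 19 higher, among them Ifit3 and Isg15), the hypoxia response -0.77 (5 of 14 lower, among them Vegfa and Slc2a1) and glycolysis -0.41 (1 of 15 lower). The 15 genes at least 4-fold higher and 13 lower rest on few cells. Of the 67 bone flap macrophages 38 had a barcode also found in another library, 4 of these as low-UMI copies. Without shared barcodes 29 cells were left, too few to compare.

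T cells of brain and galea were compared with those of blood, to see which T cell programmes were found in infected tissue. Il17a, which encodes interleukin-17A, a cytokine that draws neutrophils (ENSMUSG00000025929, chromosome 1 from 20730905 to 20734496), was at 322 CPM in brain and 3472 in galea, against 0.0645 in blood, where a single UMI was found; the ratios were 4990 (895 to 197114) and 53788 (9650 to 2124910). Its neighbour Il17f was at 160 and 467 CPM against 0.258. Il22, a cytokine gene of the same T cell type (ENSMUSG00000074695, chromosome 10 from 118204942 to 118210047), was at 2616 CPM in galea. The activation and checkpoint genes Tnfrsf4 (20.3-fold in brain, 17.4 to 23.9, and 56.9-fold in galea, 48.2 to 67.5) and Pdcd1 (36.0-fold, 26.9 to 49.4, and 98.1-fold, 72.4 to 136) were higher in both tissues. The gamma delta T cell gene Cd163l1 was 28.7-fold higher in brain. Genes of resting T cells were lower: Dapl1 (10.4-fold in brain, 84.1-fold in galea), Ccr7, which guides T cells to lymph nodes (9.93-fold and 12.1-fold), Igfbp4 (8.90-fold and 27.7-fold) and the transcription factor gene Lef1 (4.41-fold in brain).

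Of the fixed lists, the gamma delta T cell list had 9 of 9 measured members at least 2-fold higher in brain (median 3.26) and 10 of 10 in galea (3.18), with Trdc at 435 and 897 CPM against 35.1. Activation and checkpoint genes had 9 of 10 and 10 of 11 higher (medians 2.51 and 2.89), the regulatory T cell list 6 of 7 in each (1.97 and 2.86), with Ctla4 at 204 and 263 CPM against 15.9, and effector genes 8 of 14 and 12 of 17, with 2 lower in each (1.34 and 2.46). Glycolysis had 11 of 14 and 12 of 14 higher (1.58 and 2.67) and the hypoxia response 5 of 9 and 10 of 12, with 1 lower in each (1.31 and 2.82). Of 8 naive T cell genes 6 were at least 2-fold lower in brain and 7 in galea (medians -1.50 and -1.88). In total 69 genes were at least 4-fold higher and 16 lower in brain, and 210 and 62 in galea. TMM scaling moved ratios by -0.23 and -0.24 and gave 59 and 28 in brain and 175 and 92 in galea. T cells lay in different clusters: 1019 of 2097 in brain and 201 of 353 in galea were in a cluster that held 184 of 1935 in blood. S100a9, a neutrophil gene, had a UMI in 83.3% of galea T cells (2540 CPM, median depth 3815 UMIs) and in 42.8% of blood T cells (74.0 CPM, median depth 7560 UMIs), a measure of free RNA, whereas Il17a was at 1.45 CPM in galea neutrophils. In brain T cells S100a9 had a UMI in 80.4% (343 CPM, median depth 6929 UMIs). C1qa had a UMI in 46.6% of brain T cells (137 CPM) and in 1.29% of blood T cells (1.74 CPM). The counts of 4-fold genes were not filtered for free RNA, so C1qa is among the 69 genes higher in brain.

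Between the tissues, Il22 was 156-fold (139 to 175) lower in brain T cells than in galea T cells, Il13 111-fold (85.1 to 148), Il2 21.5-fold, Il17a 10.8-fold (10.4 to 11.2), Areg 11.8-fold and Csf2 7.25-fold. A few cells carried most of these UMIs in galea: the 5 richest of 353 cells held 69.3% of the Il17a UMIs, 68.5% of Il17f, 87.1% of Il22, 99.1% of Il13, 96.4% of Il2, 79.5% of Areg and 95% of Csf2. Cells with an Il17a UMI were 18.1% of brain and 17.6% of galea T cells (median depth 6929 and 3815 UMIs), against 2.12% and 0.306% of the neutrophils there (median depth 3234 and 2034 UMIs). The low-oxygen genes Bnip3 (9.77-fold), Hilpda (7.88-fold) and Ero1l (6.27-fold) were lower in brain. These are also genes of galea neutrophils, whose RNA differed between the 2 T cell groups: S100a9 was at 343 CPM in brain and 2540 in galea T cells and Cxcl2 at 41.0 and 2909. Doublets in galea are not excluded, so neutrophil RNA was not separated from these differences. In T cells the hypoxia response list had a median of -1.30 with 8 of 12 members lower, glycolysis -1 with 7 of 14 and effector genes -1.09 with 9 of 16. Activation and checkpoint genes had a median of -0.66 (4 of 11 lower, Cd69 higher), the gamma delta T cell list -0.59, the regulatory T cell list -0.36 and naive T cell genes 0.38. The histone gene Hist1h2ap was 8.85-fold (7.34 to 10.8) and Mki67, a gene of dividing cells, 3.29-fold higher in brain, while 2 of 10 members of the proliferation list were at least 2-fold higher. In total 17 genes were at least 4-fold higher and 57 lower. With the highest doublet scores also removed, 48 genes were 4-fold apart instead of 74.

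NK cells of both tissues had more Gzmc, a granzyme gene, than blood NK cells: 186 CPM in brain and 555 in galea against 1.82, or 102-fold (59.2 to 193) and 305-fold (175 to 583) higher, with 92.3% and 92.2% of the UMIs in 5 cells. Pmepa1, a target gene of TGF-beta signalling, was 65.4-fold (42.8 to 105) and 38.0-fold (22.3 to 66.8) higher. In brain NK cells Ahr was 8.87-fold, Rgs1 5.77-fold and the integrin gene Itga1, a marker of tissue-resident cells, 5.87-fold higher. The receptor gene S1pr5, needed for leaving tissue, was 4.92-fold (4.06 to 6.01) lower in brain and 7.98-fold (4.19 to 17.5) in galea, and the transcription factor gene Zeb2 3.19-fold and 9.75-fold. The cytotoxic NK list had a median of -0.62 in brain, with Prf1, also a marker used to name the class, at 556 against 1336 CPM, and of -0.38 in galea, with Gzmb at 2442 against 989 CPM. Activation and checkpoint genes had medians of 0.86 and 1.85, interferon-stimulated genes 0.88 and 1.71 (0.80 and 0.98 without members more than 5 times higher in another class), and glycolysis 0.19 and 1.44. Against galea, Gzmb was 3.72-fold and Tnfrsf9 3.74-fold lower in brain, with list medians of -1.35 for glycolysis, -1 for activation and checkpoint genes, -0.38 for interferon-stimulated genes and -0.28 for cytotoxic genes. In total 27 genes were at least 4-fold higher and 6 lower in brain than in blood, 76 and 54 in galea than in blood, and 30 and 47 in brain than in galea. Galea had 102 NK cells, in whose sum the minimum of 30 UMIs stands for 81.7 CPM, and with the highest doublet scores also removed the galea counts against blood were 49 and 58 and the brain counts against galea 30 and 20. Neutrophil RNA was found in these cells: S100a9 was at 3172 CPM in galea NK cells against 86.1 in blood NK cells, with a UMI in 85.3% and 39.3% of cells (median depth 3362 and 5976 UMIs), and Cxcl2 at 5192 against 1.54 CPM.

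B cells of brain carried genes of dividing precursors. Vpreb1 and Igll1, which encode parts of the surrogate light chain of the pre-B cell receptor and lie side by side on chromosome 16, had 547 and 285 CPM in brain; Vpreb1 was 653-fold (412 to 1105) higher than in blood, and Igll1 at least 2037-fold, since blood B cells had no UMI of it. Mki67 was 147-fold (120 to 182), the topoisomerase gene Top2a 104-fold (87.2 to 125) and the histone gene Hist1h2ap 145-fold (129 to 164) higher. All 10 measured proliferation genes were higher, with a median of 4.94. Lower in brain were Fcer2a (CD23), 7.73-fold (6.57 to 9.16), the follicle-homing receptor gene Cxcr5, 5.67-fold, and Cd55, 5.51-fold. Of 8 MHC class II genes 7 were lower (median -1.55), among them H2-Aa (929 against 3173 CPM), while oxidative phosphorylation had 13 of 24 higher (1.11) and glycolysis 5 of 12 (0.73). In total 196 genes were at least 4-fold higher and 29 lower. TMM scaling moved ratios by -0.23 and gave 158 and 51. The brain class mixed clusters of 136, 110 and 69 of its 326 cells, whereas 3290 of 3701 blood B cells lay in 1 cluster, and 69 brain cells but 1 blood cell lay in the cluster of dividing precursors. With every cell weighted equally 120 genes were 4-fold apart, and 13 of 32 named genes moved by over 1.5 times.

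Dendritic cells of brain and galea were compared with each other on 512 and 83 cells. The antigen cross-presentation genes Xcr1 (25.2-fold, 6.95 to 209, from 2 UMIs in galea) and Wdfy4 (6.58-fold, 4.29 to 10.7) and the integrin gene Itgae (7.80-fold, 4.09 to 17.1) were higher in brain. Il12b, which encodes a subunit shared by interleukin-12 and interleukin-23, was 82.8-fold (67.0 to 103) lower in brain, with 94.2% of its galea UMIs in 5 cells, and Ccl22 (8.35-fold), Tnfsf9 (13.9-fold) and Il1b (6-fold) were also lower, with 55.3%, 60.8% and 50.1% of their galea UMIs in 5 of 83 cells. Costimulation genes had a median of -1.03 (4 of 7 lower, among them Cd40 and Cd83), chemokines for mononuclear cells -1.15 (6 of 10), glycolysis -0.69 (5 of 14), interferon-stimulated genes 0.01 and MHC class II genes 0.16. There were 33 genes at least 4-fold higher and 36 lower. TMM scaling moved ratios by -0.13 and gave 25 and 43, and median-of-ratios scaling 15 and 53. Brain cells lay mostly in 1 cluster (361 of 512) and galea cells in another (47 of 83). Xcr1 and Ccl22 are also among the markers used to name the class. Il1b was also among the 10 leading genes of the neutrophil clusters that held 2793 and 1009 galea cells. Doublets in galea are not excluded, so neutrophil RNA was not separated from the difference in Il1b.

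The dendritic cell class of blood held 76 cells, of which 34 had at least 10 UMIs of Prg4 or Retnla, genes of some tissue macrophages, and 7 were copies of a barcode of another library. Retnla was at 8071 CPM in this class against 5.67 in brain and 5.02 in galea dendritic cells. Of the genes that were higher in tissue, Ifitm1 was 154-fold (113 to 216) in brain and 155-fold (114 to 218) in galea, Cxcl9 118-fold (32.7 to 979) and 238-fold (65.0 to 1975, with 76.3% of the galea UMIs in 5 cells), and Il4i1 35.6-fold (18.7 to 78.0) and 111-fold (57.9 to 244). Interferon-stimulated genes had 18 of 20 members higher in brain (median 2.32) and 16 of 19 in galea (2.28), with Isg15 at 442 and 1387 CPM against 46.1. Costimulation genes had 6 of 6 and 6 of 7 higher (2.48 and 3.76), chemokines for mononuclear cells 7 of 10 and 8 of 11, with 3 lower in each (2.98 and 3.93), and MHC class II genes 0 of 8 and 2 of 8 (0.62 and 0.52), while lipid handling had medians of -0.89 and -1.51 (5 and 7 of 11 lower, 2 higher in each). There were 127 genes at least 4-fold higher and 154 lower in brain, and 196 and 227 in galea. TMM scaling moved the galea ratios by 0.20 and gave 229 and 177, and median-of-ratios scaling 233 and 173. Without the Prg4 and Retnla cells 42 blood cells remain, too few to compare, and cell weighting moved 14 of 38 named genes in brain and 16 of 36 in galea by over 1.5 times, with the log2 ratio of Ifitm1 at 3.53 and 3.48 instead of 7.05 and 7.06.

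Monocytes of brain (117 cells) were compared with those of blood (269 cells). The immediate early gene Jun was 5.99-fold (5.28 to 6.80) higher in brain, the metallothionein gene Mt1 6.65-fold (4.47 to 10.1) and Thbs1 5.08-fold (4 to 6.48), and the transporter gene Slc12a2 4.98-fold (2.94 to 9.07) and the scavenger receptor gene Cd36 4.15-fold (2.62 to 6.94) lower. Immediate early and dissociation genes had a median of 0.67 (7 of 17 higher), phagocytic receptors 0.16, glycolysis 0.12 and interferon-stimulated genes -0.07 (none of 19 2-fold apart). There were 18 genes at least 4-fold higher and 2 lower, but 99 and 44 at the finer clustering, where the class held 777 brain and 271 blood cells, so the result rests on the clustering.

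Immature granulocytes of brain (291 cells) and galea (141 cells) had 15 genes at least 4-fold higher and 12 lower in brain. The granule protease gene Ctsg was 16.3-fold (9.06 to 32.8) higher in brain, with 98.2% of its UMIs in 5 cells and a log2 ratio of 1.85 instead of 3.62 when cells are weighted equally, Hist1h2ap 4.94-fold (4.28 to 5.73) and the cytokine gene Osm 4.61-fold (3.22 to 6.84). The granule gene Ngp was 2.81-fold (2.78 to 2.84), the actin gene Actb 2.94-fold and Anxa1 2.72-fold lower. Glycolysis had a median of -0.71 (5 of 15 lower, among them Gapdh and Hk2), the gelatinase granule list 0.38, azurophil and specific granule genes -0.02 (3 of 14 higher and 3 lower) and proliferation -0.12. With called doublets kept, or with the highest doublet scores also removed, the classes had too few cells to compare. Ctsg and Ngp are also among the markers used to name the class.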

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

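The test of barcode reuse below was chosen only after the shared barcodes were seen; the test of carried-over reads was fixed before its result.

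Apoe, the gene of an apolipoprotein that microglia and macrophages carry at high levels, went in opposite directions in neutrophils: its log2 ratio to blood was 2.62 in brain, -3.20 in galea and -3.36 in bone flap. The difference between tissues was not tested. Apoe was at 1492 CPM in brain neutrophils but at 24658 CPM in brain macrophages, so it lies under the limit of 1/5 of the highest class that kept free RNA from being named, and C1qa, another macrophage gene, had a UMI in 42.7% of brain and 0.478% of galea neutrophils (median depth 3234 and 2034 UMIs). Blood held 2878 barcodes with over 10% mitochondrial UMIs that entered no comparison. Without the cell filter, 40.9% of the 2891 left-out blood barcodes fell in the B cell class.

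The same cell barcode occurred in more than 1 library for 580 pairs of libraries and barcodes, and 249 barcodes were low-UMI copies of a barcode of another library. Chance reuse of barcodes would pair unrelated cells, but 43.6% of the pairs differed at least 10-fold in UMIs, against 3.97 to 7.76% in random pairings. Reads carried over between libraries would give the copy its partner's profile: for 96.7% of 184 copies (93.0 to 98.8%) the partner was among the 5% most similar of 200 cells. Carried-over reads therefore stay as a candidate explanation, and no biological explanation was tested. Copies made up 32 of the 35 macrophage barcodes of blood.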

How the results depend on the processing

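The settings that left out shared barcodes or the highest doublet scores were chosen after the data were seen; all others were fixed beforehand. Of 88 alternative values of the 11 class shares of at least 5% of a library 57 stayed within the counting interval, and of 206 counts of 4-fold genes 185 stayed within 1.5 times, which does not cover direction. With TMM scaling the genes higher and lower went from 193 and 41 to 17 and 256 in neutrophils of brain against galea (58 genes shared), from 200 and 484 to 487 and 107 in galea against blood (307 shared) and from 223 and 543 to 619 and 126 in bone flap against blood (349 shared). Of 7482 values of named genes 4237 stayed within the interval, 3240 moved and 5 of at least 2-fold changed sign; of 818 list medians 748 stayed within a log2 of 0.5, 69 moved further and 1 of at least 2-fold changed sign. Counting also smaller values, the sign differed for 10 gene values and 21 list medians, 11 of the latter after TMM scaling. The cause was not tested for any of the values below. Leaving out a replicate is not possible.

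Shares (%) moved as follows. With the stricter filter brain had 9.42 neutrophils, 14.3 macrophages, 30.7 microglia and 5.74 dendritic cells, galea 85.3 neutrophils, bone flap 97.9 neutrophils, and blood 24.8 neutrophils, 21.8 NK cells and 22.6 B cells. Without a filter brain had 6.48 neutrophils, 12.4 macrophages and 26.4 microglia, galea 87.6 neutrophils, and blood 10.03 neutrophils, 21.5 T cells and 11.6 NK cells. With doublets kept brain had 6.89 neutrophils and 33.6 microglia, and blood 12.4 neutrophils and 21.5 T cells. With the highest doublet scores removed brain had 7.10 neutrophils and 33.3 microglia, and without shared barcodes brain had 8.76 and bone flap 98.8 neutrophils. With each library clustered on its own brain had 11.2 neutrophils, 6.64 macrophages and 17.4 T cells, galea 71.2 neutrophils, and blood 19.3 T cells and 13.8 NK cells. At resolution 2 brain had 6.72 macrophages.

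Counts of 4-fold genes moved as follows. Without the floor they were 380 in B cells, 60 in NK cells of brain against blood, 283 of galea against blood and 171 of brain against galea, 136 in T cells of brain against blood, 672 in dendritic cells of galea against blood and 122 of brain against galea, 45 in immature granulocytes and 38 in monocytes. With each cell thinned to 1000 UMIs they were 81 in B cells, 210 in NK cells of galea against blood, 99 in dendritic cells of galea against blood and 109 of brain against galea, 118 in macrophages of galea against bone flap and 10 in monocytes; the class sums then stayed unequal, so that 30 UMIs stood for 306 CPM in galea and 26.9 in blood NK cells, 429 in blood and 59.4 in brain dendritic cells, and 500 in bone flap and 53.4 in galea macrophages, and these counts cannot be read as an effect of depth. The genes higher and lower then were 21 and 189 (76 and 54 unthinned) in NK cells of galea against blood and 89 and 12 (30 and 47) of brain against galea, 199 and 32 (127 and 154) in dendritic cells of brain against blood and 101 and 8 (33 and 36) of brain against galea, 111 and 7 (15 and 13) in macrophages of galea against bone flap, and 2 and 8 (18 and 2) in monocytes. With equal cell weights B cells had 120. With the highest doublet scores removed, brain against galea gave 50 in NK cells and 48 in T cells. At resolution 2 macrophages had 17 for galea against bone flap and 179 for brain against galea, and monocytes 143.

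Signs of values of at least 2-fold changed for Hspa1a (-0.72) and Ly6i (2.56) in monocytes at resolution 2, Cd80 in dendritic cells of brain against galea with thinned cells (0.0042), Mpo in immature granulocytes with equal cell weights (-0.0877) and thinned cells (-0.44), and the oxidative phosphorylation median in bone flap neutrophils with TMM scaling (0.0833). Smaller neutrophil medians whose sign TMM scaling turned with a move of over 0.5 were oxidative phosphorylation in galea against blood (0.18) and brain against galea (-0.12), the gelatinase granule list in galea (0.17) and bone flap (0.68) against blood and in brain against galea (-0.19), and interferon-stimulated genes in brain against galea (-0.88). Chemokines for mononuclear cells in brain against galea neutrophils turned to 0.20 when members with at least 3 UMIs were used. Immature granulocytes could not be compared with doublets kept (33 and 17 cells) or the highest doublet scores removed (33 and 18), nor macrophages of galea and bone flap without shared barcodes (29 bone flap cells). The galea's median of 2124 UMIs per barcode limits what can be seen there.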

Other observations

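The tests of carried-over reads, blood cells and free RNA in this part were chosen after the results were seen. Those of developing B cells and cavity macrophages were fixed before their results.

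Among brain granulocytes 26.6% (24.0 to 29.4%) were immature, against 0.863% in blood (0.415 to 1.58%). Of brain B cells 21.2% (16.9 to 26.0%) lay in the cluster of dividing precursors, against 0.0270% of blood B cells. These shares argue against blood left in the brain as the source of most of these immature cells and precursors. They do not bear on blood among the other brain cells: 256 of 801 brain neutrophils lay in the main blood neutrophil cluster. In galea the precursor share was 29.0% of 31 B cells (14.2 to 48.0%) and the immature share 1.33% of granulocytes (1.12 to 1.57%), which overlaps blood, and bone flap had 0 of 6585. Of 432 immature granulocytes of brain and galea 0.926% (0.253 to 2.35%) had a barcode that another library also held, which argues against reads carried over between libraries. Cells mixed before they received a barcode would not share one, so this was not tested. The immature share in brain, in which unnamed cells were not counted, differed strongly between settings. It was 21.7% at Leiden resolutions of 0.5 and 2 and without shared barcodes, and 21.97% with the stricter filter. With doublets kept it was 4.50% (3.12 to 6.26%) against 0 of 1120 in blood. With each library clustered on its own it was 3.17% (2.23 to 4.36%) against 0 of 1093. The lower limit of the share in brain stayed above the upper limit in blood in these settings, while its size did not hold. The cause was not tested. All 4 of 4 genes tested for developing B cells rather than dividing mature B cells were over 10-fold higher in brain than in blood B cells: Rag1 (124 against 1.07 CPM), Rag2 (30.9 against 0), Dntt (194 against 0.0931) and Vpreb2 (75.4 against 0). A hypothesis is that brain samples may hold developing leukocytes, which the CD45 gate would not remove; where they came from was not tested.

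Retnla, Prg4 and Saa3 in the dendritic cell class of blood came from few cells. Of 35 blood cells with at least 10 UMIs of Prg4 or Retnla 8.57% (1.80 to 23.1%) had a barcode that another library also held, which argues against reads carried over between libraries as the source of most. Cells mixed before they received a barcode were not tested here either. Of 15903 UMIs of the 3 genes 96.6% lay in these 35 cells, which argues against free RNA in the blood library. In a list of cavity macrophage genes, 8 of 8 were at least 4-fold higher in the 21 Prg4 cells than in the 55 other cells of the class (macrophages of a body cavity collected with the blood). The most abundant were Icam2 (785 against 23.1 CPM), F5 (592 against 12.6), Ltbp1 (493 against 0) and Selp (463 against 0), with Gata6 at 107 against 0. Of the 55 other cells, the 42 with under 10 UMIs of both Prg4 and Retnla held all UMIs of Timd4 (9). Gata6, Garnl3, Selp, Vsig4 and Ltbp1 had 0 UMIs in the 55 cells. The cells of the class selected by Retnla alone thus held no UMI of these 6 genes. They did hold UMIs of F5 (12 in the 55 cells, 3 in the 42) and Icam2 (22 and 10). A hypothesis, for the Prg4 cells only, is that macrophages of a body cavity may have been collected with the blood, which the CD45 gate would not remove. What the cells selected by Retnla alone are was not tested.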
